A study of Mus musculus with 3 samples.

How the data were processed

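RNA-seq of 3 sorted mouse cell populations was analysed from the gene tables the authors deposited. Per the labels, cells were sorted from wild-type C57BL/6J mice after intranasal LPS, lysed in TRIzol LS, and made into libraries with a low-input RNA kit. The deposited values are FPKM, fragment numbers scaled to transcript length and to the mapped fragments of the library, as the file headers name them. Per the submitters' processing notes, the tools were TopHat2 2.0.8, Bowtie2 2.1.0 and Cufflinks 2.1.1 with the mm9 mouse genome; their settings are not given in the sources used here. FPKM values are estimates and not counts, so no count model was used.

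Groups were taken from the sort gate, tissue and day in the labels, giving 3 groups of 1 library. With 1 library per group no test, p-value or standard deviation could be given, and tissue, day and gate cannot be separated from the group where they differ together. The tables list 23234 genes each, with 0 repeated symbols. Values above 0 and below 1e-06 FPKM, of which there were 32 in DP, 20 in nasal neutrophils and 43 in blood neutrophils, were taken as numerical residue and set to 0, a choice made after the values were seen. Values were used as deposited on the log2(FPKM + 1) scale, which understates the ratio of low genes. A gene was tested where its mean over the 3 libraries was 1 FPKM or more (10719 genes), and a gene counted as higher or lower at 4-fold, a log2 ratio of 2. FPKM sums were 637561.3 in DP, 620230.4 in nasal neutrophils and 663027.1 in blood neutrophils. An exact 0 can be a failed estimate, so no fold of a single gene is given against a library listed at 0, but the 4-fold counts, list medians and percentiles keep such genes on the log2(FPKM + 1) scale. S100a8 was at 0 in blood, Actr3 in nasal neutrophils and Mbnl1 in DP while at 10 FPKM or more in both others, as were 83 genes in blood altogether.

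Depth was estimated from the steps between low values times transcript length, over genes with a single transcript of more than 1500 nt. A gene was counted at a step where it lay within 6% of it. Steps gave 0.0179 FPKM for 1 fragment per kb in DP, 0.078 in nasal neutrophils and 0.0182 in blood neutrophils. In nasal neutrophils 164 genes lay at that step and 8 at 0.5 of it, in DP 120 and 21, and in blood neutrophils 108 and 5, so the step was least clear in DP. The commonest ratios of low values were 0.987 (60 genes) for DP over blood, 0.473 (67 genes) and 0.236 (59 genes) for DP over nasal neutrophils, and 2.087 (27 genes) for nasal over blood neutrophils. Such ratios fix relative depth only up to a ratio of whole fragment numbers, so the depths rest on the steps and are approximate. Transcript lengths came from the GENCODE M21 annotation, of another build than mm9, and were used as lengths only, with 98.7% of tested genes matched by symbol or older symbol. No coordinates are reported.

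Before the data were examined, 38 gene lists, the rules for naming genes and the alternatives were fixed. A list with at least 5 measured members was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. It was said to stand apart at a percentile of 2.5 or less or 97.5 or more, which describes these libraries and is not a p-value. Sort markers and mast cell and basophil markers had too few measured members to be ranked. Genes were named if they were sort genes or neurotrophic factors, if they were among the 10 highest or 10 lowest log2 ratios at a mean of 5 FPKM or more, or if they were among the 4 members with the largest ratio in a list that stood apart or marked another cell type. Camp in the plot of levels, and Csf3r, Il1r2, Gng13, Epcam, Cnga2, Cyp2g1, Ncam1, Ptgs1, Cyp4f18 and Mbnl1, lie outside these rules and were chosen after their values were seen. Listed genes without a row of that name (Ly6g, Ear3, Trac, Mzb1, Azu1, Pirb and Emc7) were not analysed here.

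Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean of 5 FPKM or more, values rescaled to a sum of 1000000, ratios centred on the median, upper-quartile scaling, random lists without matching and, for the counts over the 3 libraries, a 2-fold threshold. Added after seeing the data were ratios corrected for transcript length in 20 length bins, DP against nasal neutrophils over genes at 1 FPKM or more in blood, the omission of genes listed at 0 in 1 library and at 10 or more in both others, the omission of genes at 0 in either library of a comparison, and the tumour neutrophil list without Siglec5, a gene of the sort. The list and count steps were checked on simulated values with 200 genes changed by 16-fold among 10719 and noise of 0.4 on the log2 scale. For DP against nasal neutrophils 99.5% of changed genes were recovered, for nasal against blood neutrophils 100% and for DP against blood 98.5%; of unrelated lists, 3.5%, 3.5% and 5.5% fell outside the central 95%. The noise and the fold were chosen for the simulation and are not estimates from these libraries. Unrelated lists were drawn at random from genes with independent noise, so the check covers only whether the steps run as meant. Genes of a real list may vary together, which the simulation does not cover. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.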

Results

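RNA was sequenced from 3 sorted mouse cell populations after lipopolysaccharide (LPS), a bacterial cell wall component that triggers inflammation, was instilled into the nose of wild-type C57BL/6J mice (10 µg in 10 µL). Nasal double-positive cells (DP) carried CD45, Ly6G and SiglecF and were taken from the nose 2 days after LPS. Nasal neutrophils carried CD45 and Ly6G without SiglecF and were taken from the nose 1 day after LPS, and blood neutrophils were sorted with that same gate from blood 1 day after LPS. There was 1 library per group, so no difference below has a replicate error or a test, and the day and the gate of the DP library differ from those of the others along with the group. The sample code in the labels of the nasal neutrophil library lies apart from the adjacent codes of the other libraries; whether it was a separate batch is not stated, and a batch could not be told apart from the group in the comparisons with that library. Each library listed FPKM values for the same 23234 genes. Genes at 1 FPKM or more numbered 11294 in DP, 10460 in nasal neutrophils and 7706 in blood neutrophils. The 100 most abundant genes held 37.9% of the FPKM sum in DP, 53.4% in nasal neutrophils and 56.8% in blood neutrophils. Steps between the low values put the depth at about 55700000 fragments for DP, 12800000 for nasal neutrophils and 54900000 for blood neutrophils, so that 1 FPKM in a transcript of 1 kb rests on about 56, 13 and 55 fragments.

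The genes of the sort were read first. Siglec5, the name under which the tables list the SiglecF gene, stood at 167.8 FPKM in DP, 9.92 in nasal neutrophils and 18.7 in blood neutrophils. Ptprc, which encodes CD45, stood at 445.1, 136.7 and 718.8 FPKM in the same order. Ly6g was not analysed here. Transcripts of nasal tissue were present in both nasal libraries. Omp, the olfactory marker protein of mature olfactory neurons, was at 244 FPKM in DP and 233.7 in nasal neutrophils and was listed at 0 in blood. The keratin gene Krt18 was at 289.7, 131.9 and 0.33 FPKM in DP, nasal and blood neutrophils. Of 1118 olfactory receptor genes, 688 reached 0.1 FPKM in DP, 578 in nasal neutrophils and 8 in blood neutrophils. Markers of eosinophils, which also carry SiglecF, were low: 5 of 16 reached a mean of 1 FPKM. Among them Ear2 stood at 0.43 FPKM in DP, 11.5 in nasal neutrophils and 1.34 in blood, while Alox15 (7.98 in DP, 2.73 in nasal neutrophils and listed at 0 in blood) and Ccr3 (1.92, 0.49 and 4.15) were higher in DP than in nasal neutrophils.

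The comparison of DP with nasal neutrophils asks how SiglecF-positive and SiglecF-negative Ly6G-positive cells of the nose differ. Granule protein, chemokine and NF-kappaB target genes were lower in DP, and genes of oxidative phosphorylation were higher. Lcn2, which encodes an iron-scavenging granule protein, stood at 70.2 FPKM in DP against 3577 in nasal neutrophils. The cytokine gene Osm stood at 49.8 against 835.5 FPKM. Ltc4s, which encodes the enzyme that makes leukotriene C4, stood at 417.9 FPKM in DP against 4.61 in nasal neutrophils and 0.80 in blood neutrophils. Of 10719 tested genes, 903 were at least 4-fold higher in DP and 388 at least 4-fold lower, of which 80 and 30 were listed at 0 in the lower library. The median log2 ratio of all tested genes was 0.57, and with ratios centred on it the counts were 360 higher and 773 lower, so the balance of directions rests on the scaling. With upper-quartile scaling they were 350 and 734.

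Among the gene lists fixed in advance, 36 had enough measured members to be ranked, and 1 stood above and 25 below the central 95% of random lists matched on expression, where 1.8 would fall outside by chance for unrelated lists. Many lists share members, as the granule and neutrophil marker lists share Lcn2, Mmp8 and Ngp, so in no comparison is such a count one of separate results. In this comparison the random lists centre near the median of all tested genes, so a list with a median near 0 can stand below them. Being matched on expression, they need not centre there in the others. For nasal against blood neutrophils, where the median of all tested genes was 0.41, a granule list median of 0.02 lay at percentile 73.2. Ranks are not affected by centring. The lowest median belonged to secondary and tertiary granule proteins, at -2.05 (percentile 0), with 16 of 30 genes at least 4-fold lower in DP and 0 at least 4-fold higher. Besides Lcn2, the collagenase gene Mmp8 stood at 17.7 FPKM in DP and 507.6 in nasal neutrophils and the chitinase-like gene Chi3l3 at 16.7 and 449.4. Padi4, a member of the fixed list whose product is an enzyme that citrullinates histones, stood at 4.53 and 117.7. The neutrophil marker list had a median of -1.99 (percentile 0), with Retnlg at 142.9 FPKM in DP and 4692 in nasal neutrophils and Ngp at 266.6 and 3993. Primary granule genes had a median of -0.53 (percentile 0.81), with 7 of 10 within 2-fold, among them Mpo (3.9 and 7.37 FPKM) and Elane (8.59 and 8.91). Serpinb1a, at 5.21 and 43.4 FPKM, was the 1 gene of that list at least 4-fold lower. Primary granule genes no longer stood apart at a mean of 5 FPKM or more (percentile 9.97) or over genes at 1 FPKM or more in blood (8.18). The list of neutrophil ageing and retention had a median of -1.46 (percentile 0.1), with the integrin gene Itgal at 16.3 FPKM in DP and 97.4 in nasal neutrophils.

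Inflammatory mediators were lower in DP as groups. Markers of several other leukocytes were lower in the same comparison, though T and NK cell markers were not (median 0.43, percentile 46.4). Macrophage markers had a median of -0.75 (percentile 0.08, and 8.85 over genes at 1 FPKM or more in blood), monocyte and dendritic cell markers -0.88 (percentile 0.06) and B and plasma cell markers -1.53 (percentile 0), with Ly6c2 at 10.4 FPKM in DP and 261.7 in nasal neutrophils and Cd79a at 2.19 and 23.2. Chemokine genes had a median of -1.67 (percentile 0) with 0 of 22 at least 4-fold higher and 7 at least 4-fold lower, among them Cxcl3 at 38.4 FPKM in DP and 722.3 in nasal neutrophils and Cxcl10 at 29.5 and 411. Cytokine genes had a median of -1.16 (percentile 0), with Il6 at 1.14 and 20.1 FPKM and Il10 at 0.24 and 10.9, while Il33 was higher in DP at 50.3 against 6.16. Il33 was listed at 0 in blood. Whether its value came from nasal tissue RNA, of which some transcripts were also higher in DP, was not tested. For NF-kappaB targets the median was -1.58 (percentile 0), with 10 of 29 at least 4-fold lower and 0 higher, including Nfkbiz (86.7 and 1121 FPKM) and Relb (5.18 and 54.7). Immediate early and heat shock genes had a median of -0.83 (percentile 0, and 4.42 over genes at 1 FPKM or more in blood), with Fosb at 5.08 and 112.3 FPKM. Checkpoint and suppressive molecules had a median of -1.17 (percentile 0.01), with Cd274, which encodes PD-L1, at 20.5 and 409.4 FPKM and Nos2 at 0.55 and 30.3. Interferon response genes had a median of -0.95 (percentile 0), with Oasl1 at 4.77 and 119 FPKM and Rsad2 at 8.89 and 154.7. Chemoattractant receptors had a median of -0.98 (percentile 0.01), with the formyl peptide receptor gene Fpr1 at 98.9 and 985.8 FPKM, and pattern recognition receptors one of -0.62 (percentile 0.04), with Nlrp3 at 23.4 and 378.4 and Tlr2 at 39.7 and 596.8. Of the 22 pattern recognition receptors, 9 were at least 2-fold lower and 3 at least 2-fold higher in DP.

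Oxidative phosphorylation was the list above the random range, with a median of 1.84 (percentile 100) and 16 of 35 genes at least 4-fold higher in DP and 0 at least 4-fold lower. Some nasal tissue transcripts were also higher in DP: summed olfactory receptor genes stood at 1231 against 392.5 FPKM, Bpifa1 at 272.6 against 38.2 and Gap43 at 49.7 against 9.96, while Omp was near equal. Others were lower in DP, such as Foxj1 at 0.36 against 6.04 FPKM. Of the 23 measured epithelial and olfactory markers, 14 were higher and 9 lower in DP, 4 and 2 of them at least 4-fold. Ndufa1, a complex I subunit gene, stood at 350.9 FPKM in DP and 29.3 in nasal neutrophils, Uqcrq of complex III at 718.4 and 64.9, and Cox7b of complex IV at 120 and 10.3. Short transcripts were higher in DP in general: the median log2 ratio was 1.19 for 1186 genes of 400 to 1000 nt and 0.39 for 6223 genes over 2000 nt. With ratios corrected for transcript length, an alternative chosen after seeing the data, the median of this list was 1.44 and its percentile 100. Cytosolic ribosomal protein genes, also short, had a median of 0.87 (percentile 84.8). Other genes with large ratios were the short-transcript genes Atp5k (859.2 and 22.6 FPKM), Dpm3 (212.7 and 5.64) and Lsm7 (326.2 and 10.7), and Bola2 (328 and 6.27). The Bola2 value would be uncertain if its reads were divided with close copies, which was not tested. Expi, which encodes an extracellular proteinase inhibitor, stood at 29517 FPKM in DP, 472.2 in nasal neutrophils and 27.5 in blood. Odam (42.1 FPKM in DP and 0.64 in nasal neutrophils) and Sval2 (51.6 and 1.53) were also among the highest ratios and were listed at 0 in blood. Whether the values of Expi, Odam and Sval2 came from nasal tissue RNA was not tested. Snai1 (1.95 and 133.7 FPKM), Prok2 (2.61 and 157.7), the haem oxygenase gene Hmox1 (12.7 and 446.6) and the matrix protein gene Thbs1 (13.5 and 409.7) were among the lowest in DP. Ubb and Rps27 were listed at 0 in DP, and Actr3 at 0 in nasal neutrophils, so their ratios are not given.

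**Figure D1:**
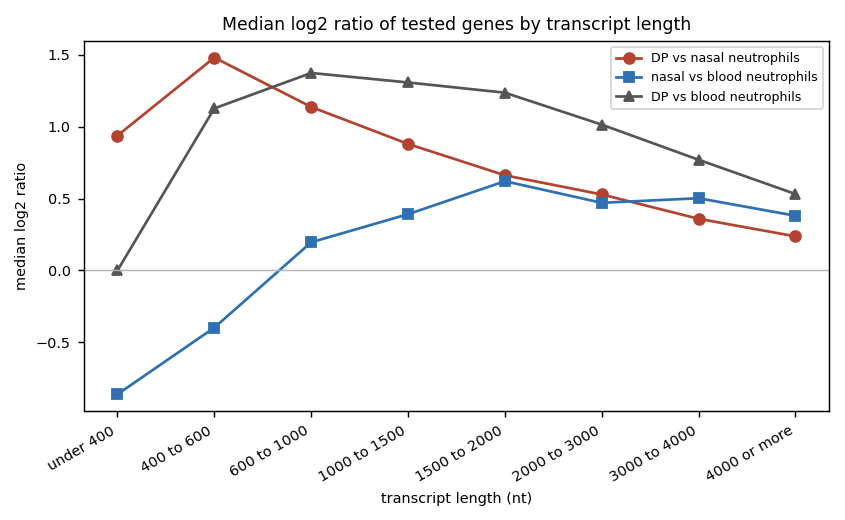
Median log2 ratio of tested genes in 8 bins of transcript length in nt, 1 line per comparison. DP against nasal neutrophils falls from 1.48 at 400 to 600 nt to 0.24 at 4000 nt or more.

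A list of genes reported for SiglecF-high neutrophils of tumours divided between the libraries. Ltc4s was higher in DP, as was Siglec5, which the gate selects, while Cd274 and Tnf (60.3 FPKM in DP and 372.8 in nasal neutrophils) were lower, and the list median was -0.9 (percentile 0.24, and 0.23 without Siglec5). Of 47 neurotrophic and growth factor genes, only 17 reached a mean of 1 FPKM and were ranked in each comparison. These had a median of 0.18 (percentile 16.1), and with no filter all 47 lay at percentile 1.26. In that list Mdk, which encodes the growth factor midkine, was at 14.9 FPKM in DP and 2.3 in nasal neutrophils, Hgf was at 5.76 and 1.06, and Thbs1 and Osm were lower in DP as given above. Whether nasal tissue RNA gave a part of the Mdk value was not tested.

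**Figure D2:**
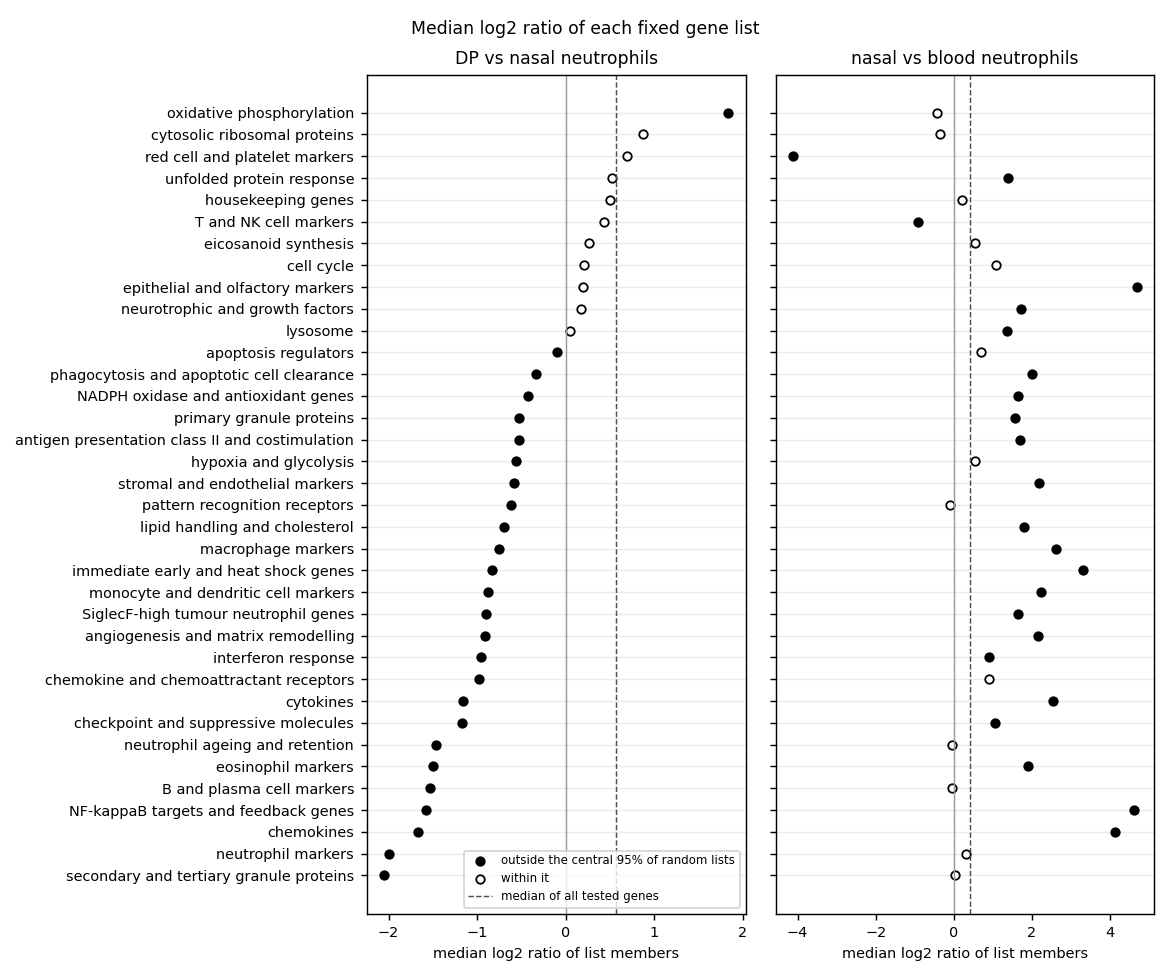
Median log2 ratio (FPKM + 1) of each ranked gene list, 1 point per list, for DP against nasal neutrophils (left) and nasal against blood neutrophils (right), ordered by the left panel. Filled points lie outside the central 95% of matched random lists. The dashed line is the median of all tested genes (0.57 and 0.41), on which matched random lists need not centre. Granule proteins are lowest at left (-2.05) and oxidative phosphorylation highest (1.84).

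The comparison of nasal with blood neutrophils sets the same gate and day side by side in both places. The nasal neutrophil library held far more transcripts of chemokines, NF-kappaB targets and immediate early genes. It also held transcripts of other cells, given below, and whether such cells gave a part of these values was not tested. Cxcl2, a neutrophil attractant, stood at 12756 FPKM in nasal and 3.6 in blood neutrophils, and the alarmin gene Il1a at 2575 and 0.15. Retnlg was lower, at 4692 against 20894 FPKM. In all, 1408 genes were at least 4-fold higher and 346 at least 4-fold lower in the nose, of which 320 and 72 were listed at 0 in the lower library, where a 0 can be a failed estimate. Without genes at 0 in either library they were 1088 and 274. The median log2 ratio was 0.41, and with centred ratios 968 were higher and 609 lower.

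Of the 36 ranked lists, 21 stood above and 2 below the random range. NF-kappaB targets had a median of 4.6 (percentile 100), with 25 of 29 at least 4-fold higher and 0 lower, including Ptgs2, which encodes an inducible prostaglandin synthase (738.4 against 2.01 FPKM), and Tnfaip3, a feedback inhibitor (632.8 against 2.32). Chemokines had a median of 4.12 (percentile 100), with 19 of 22 at least 4-fold higher, 8 of them listed at 0 in blood, including Ccl3 (4615 against 1.89 FPKM) and Ccl4 (6729 against 8.36). Immediate early and heat shock genes had a median of 3.3 (percentile 100), with 28 of 34 at least 4-fold higher, 5 of them listed at 0 in blood, among them Egr1 (1198 against 0.17 FPKM) and Dusp2 (195.6 against 0.39). Hspa1a stood at 208.9 against 0.37 FPKM, with reads that may be divided with its near-identical copy. Cytokines had a median of 2.53 (percentile 100), with 13 of 25 at least 4-fold higher, 4 of them listed at 0 in blood. Without genes at 0 in either library the cytokine median was 1.79 (percentile 99.98). Tnf stood at 372.8 against 1.89 FPKM and Il23a at 261.3 against 0.06, and Csf3 at 188.3 and listed at 0 in blood. Antioxidant and oxidase genes had a median of 1.65 (percentile 99.99), with Sod2 at 277.5 against 5.87 FPKM. Unfolded protein response genes had a median of 1.38 (percentile 99.99), with Ppp1r15a at 763.5 against 7.28 FPKM. Angiogenesis and matrix genes had a median of 2.14 (percentile 100), with Tgm2 at 414.8 against 14.8 FPKM. The 17 measured genes of the 47 in the neurotrophic and growth factor list had a median of 1.71 (percentile 99.99). Among them Thbs1 stood at 409.7 against 0.61 FPKM, Osm at 835.5 against 16.4 and Inhba at 17.8 against 0.35. The tumour neutrophil list had a median of 1.64 (percentile 99.82), with Icam1 at 412 against 4.64 FPKM.

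Markers of other cells moved with this comparison. The epithelial and olfactory list had a median of 4.69 (percentile 100), with 20 of 23 genes at least 4-fold higher in the nose, 12 of them listed at 0 in blood, and a median of 4.8 (percentile 100) over the 10 genes above 0 in both. It included the odorant-binding protein gene Obp1a (1329 against 0.42 FPKM). Macrophage markers had a median of 2.6 (percentile 100), with C1qb at 80.9 FPKM and listed at 0 in blood, and stromal and endothelial markers one of 2.17 (percentile 99.96). Of 9 macrophage markers at least 4-fold higher, 4 were listed at 0 in blood. Without genes at 0 in either library the macrophage median was 1.64 (percentile 99.54) and the stromal and endothelial one 1.57 (percentile 98.92). Monocyte and dendritic cell markers had a median of 2.23 (percentile 99.98), with Ccr2 at 15.8 against 0.76 FPKM. Red cell and platelet markers were lower, with a median of -4.12 (percentile 0). Haemoglobin genes, whose reads may be divided among close copies, were 4 of its 9 measured genes, and Alas2, the first enzyme of haem synthesis in red cell precursors, stood at 0.16 against 19.2 FPKM. T and NK cell markers were the other list below, at -0.91 (percentile 0.05), with low levels such as Cd3d at 1.89 against 4.44 FPKM. Primary granule genes were higher, with a median of 1.57 (percentile 98.93, 93 at a mean of 5 FPKM or more, and 97.19 without genes at 0), at low levels such as Mpo at 7.37 FPKM and listed at 0 in blood. Secondary and tertiary granule genes did not stand apart, with a median of 0.02 (percentile 73.2), with Ltf at 1324 against 56.6 FPKM and Stfa1, a member of a multigene family, at 35 against 379.4. S100a8, an abundant neutrophil gene, was listed at 0 in blood and at 29818 FPKM in nasal neutrophils, and no ratio is given.

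**Figure D3:**
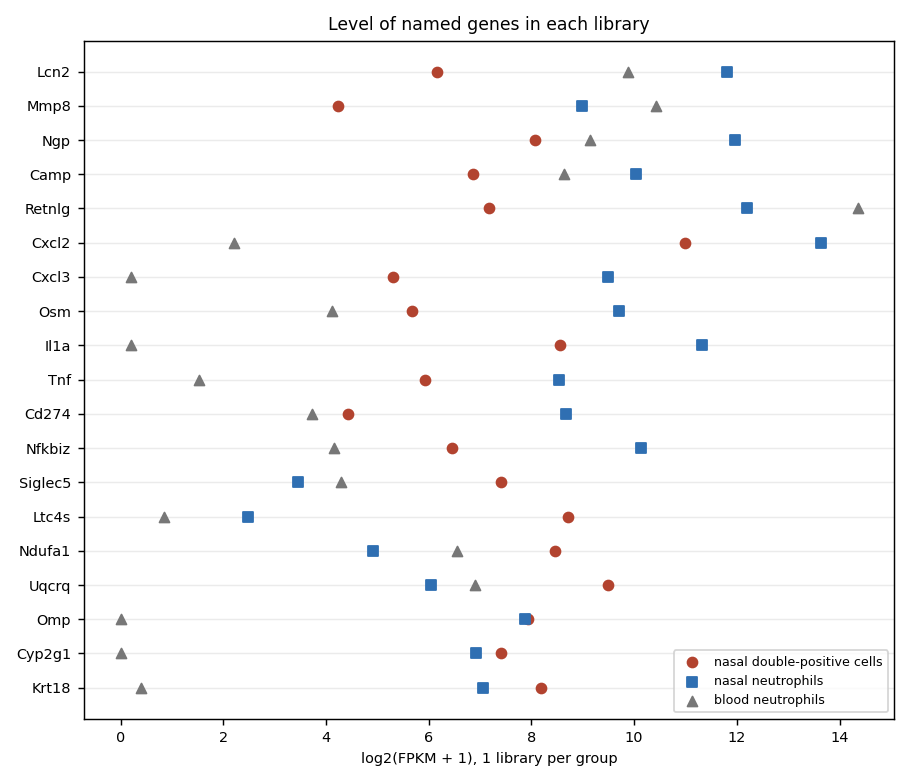
Level of 19 named genes in each library on a log2(FPKM + 1) axis, 1 point per library (circle DP, square nasal neutrophils, triangle blood neutrophils). Lcn2 is at 70.2 FPKM in DP and 3577 in nasal neutrophils, Ltc4s is highest in DP, and Omp is at 244 FPKM in DP, 233.7 in nasal neutrophils and 0 in blood.

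The comparison of DP with blood neutrophils sets the nasal SiglecF-positive cells against the circulating cells. Chemokine and immediate early genes were higher in DP than in blood, and secondary and tertiary granule genes were lower. Cxcl2 stood at 2025 FPKM in DP and 3.6 in blood neutrophils and Egr2 at 180.8 and 0.77, while Mmp8 stood at 17.7 and 1369 and the calcium-binding protein gene S100a11 at 307.9 and 11622. At least 4-fold higher were 2577 genes and 383 were at least 4-fold lower, of which 559 and 54 were listed at 0 in the lower library, with a median log2 ratio of 0.95. With centred ratios the counts were 1116 and 971, and with upper-quartile scaling 1594 and 788. Of the 36 lists, 8 stood above and 10 below the random range. Those above were epithelial and olfactory markers (median 4.94, percentile 100), chemokines (2.72, 100), immediate early genes (2.62, 100), the tumour neutrophil list (2.1, 99.83, and 98.3 without Siglec5), NF-kappaB targets (2.05, 99.98), neurotrophic and growth factors (1.89, 99.04, and 91.7 with no filter), the unfolded protein response (1.65, 98.97) and oxidative phosphorylation (1.56, 99.65, and 97.4 without matching). Spp1, which encodes osteopontin, stood at 196.7 against 7.75 FPKM, the growth factor gene Hbegf at 14 against 0.06 and Mdk at 14.9 against 0.14. Ffar2, a short-chain fatty acid receptor gene of the tumour neutrophil list, stood at 41.8 FPKM in DP and 0.95 in blood. Secondary and tertiary granule genes had a median of -2.08 (percentile 0), with 16 of 30 at least 4-fold lower, while primary granule genes did not stand apart (median 1.19, percentile 69). Pattern recognition receptors had a median of -0.65 (percentile 0.07), with 3 of 22 at least 4-fold lower and 4 at least 4-fold higher, of which Clec4n stood at 1670 against 70.2 FPKM. Interferon response genes had a median of -0.13 (percentile 0.85), below the median of all genes. The other lists below were red cell and platelet markers (-4.3, percentile 0), neutrophil ageing and retention (-1.66, 0.03), neutrophil markers (-1.55, 0.03), B and plasma cell markers (-1.19, 0), T and NK cell markers (-0.55, 0.26), chemoattractant receptors (-0.18, 0.55, and 6.29 with no filter) and eosinophil markers (-0.27, 1.71, and 5.43 without matching). Genes with some of the highest ratios were Lcn11 at 5449 against 0.23 FPKM, the secretoglobin gene Scgb1c1 at 1294 against 0.15 and Stoml3, an olfactory neuron gene, at 1104 against 0.10.

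Across the 3 libraries, 557 genes were at least 4-fold higher in DP than in both neutrophil libraries, where 217.1 would be expected of independent lists, and 98 were lower than in both (13.9 expected). With upper-quartile scaling these were 195 and 241, so the balance of directions rests on the scaling. Both nasal libraries exceeded blood at 944 genes (338.5 expected) and lay below it at 172 (12.4 expected; 275 with upper-quartile scaling). Nasal neutrophils exceeded both others at 202 genes (51 expected; 304 with upper-quartile scaling) and lay below both at 73 (29.1 expected). Each of these pairs of comparisons shares a library, which by itself can raise the counts above those of independent lists. How much of the excess comes from that was not tested, so the excess is not read as a shared effect.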

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

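Centring cannot move a list percentile and is left out of the next counts of lists. Of 500 values of lists that stood apart, taken under the other alternatives run for lists, 470 still did, 29 no longer did and 1 crossed the middle of the random range; of 302 values of lists that did not stand apart, 26 came to do so. Of 1649 log2 ratios of named genes taken under alternatives, 480 moved by more than 1.5-fold, and 0 of those at least 4-fold in size changed sign. A pseudocount cannot change a sign, and centring shifted log2 ratios by only 0.57, 0.41 or 0.95. A log2 ratio of 2 could not turn under these settings, so the absence of sign changes says little about the directions. The summing of rows with the same symbol was void because no symbol repeats, no replicate can be left out with 1 library per group, and dropping the filter cannot add 4-fold genes at a pseudocount of 1. No paired analysis was possible because each group has 1 library. The cause of the changes below was not tested.

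Counts at least 4-fold higher and lower moved with the scaling. Centred ratios gave 360 higher and 773 lower for DP against nasal neutrophils, 609 lower for nasal against blood neutrophils, and 1116 higher and 971 lower for DP against blood. Upper-quartile scaling gave 350 and 734 for DP against nasal neutrophils and 1594 and 788 for DP against blood, with 195 genes above and 241 below both neutrophil libraries in DP, 275 below blood in both nasal libraries and 304 above both others in nasal neutrophils. A pseudocount of 0.1 gave 1390 higher for DP against nasal neutrophils and 2886 for nasal against blood. A pseudocount of 5 gave 441 and 203 for DP against nasal neutrophils, 470 and 215 for nasal against blood and 941 higher for DP against blood, with 256 above and 54 below both in DP, 269 above blood in both nasal libraries, and 97 above and 38 below both others in nasal neutrophils. A mean of 5 FPKM or more gave 1630 higher for DP against blood. Without genes at 0 in either library the counts were 823 and 358 for DP against nasal neutrophils, 1088 and 274 for nasal against blood and 2018 and 329 for DP against blood. A 2-fold threshold gave 2660 above and 411 below both in DP, 2872 above and 569 below blood in both nasal libraries, and 739 above and 613 below both others in nasal neutrophils.

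List percentiles that came within the random range are given by setting. For DP against nasal neutrophils, genes at 1 FPKM or more in blood put macrophage markers at 8.85, primary granules at 8.18, phagocytosis at 21 and immediate early genes at 4.42; a mean of 5 FPKM put primary granules at 9.97, phagocytosis at 3.12 and apoptosis regulators at 2.6; the length correction put phagocytosis at 2.71 and the omission of genes listed at 0 put it at 6.36. For nasal against blood neutrophils, no filter put checkpoint molecules at 41.53, across the middle of the range, and eosinophil markers at 70.3. There a mean of 5 FPKM put primary granules at 93, checkpoint molecules at 52.5 and phagocytosis at 94.3, and the length correction put checkpoint molecules at 97.2. The omission of genes at 0 in either library put primary granules at 97.19, checkpoint molecules at 51.81 and phagocytosis at 95.04, and left too few eosinophil markers to rank. A pseudocount of 0.1 put eosinophil markers at 91.3 and primary granules at 95.8, and one of 5 put eosinophil markers at 93.1 and checkpoint molecules at 91.2. Unmatched random lists put eosinophil markers at 97.4, interferon response genes at 95.6 and checkpoint molecules at 95.4. For DP against blood, no filter put chemoattractant receptors at 6.29 and neurotrophic factors at 91.7, a pseudocount of 5 put eosinophil markers at 3.52, and unmatched lists put eosinophil markers at 5.43 and oxidative phosphorylation at 97.4. The length correction, the blood filter, both omissions of genes at 0 and the omission of Siglec5, a gene of the sort, were chosen after seeing the data. Without Siglec5 the tumour neutrophil list lay at 0.23 for DP against nasal neutrophils, 99.81 for nasal against blood and 98.3 for DP against blood. At about 12800000 fragments the nasal neutrophil library was the shallowest, so its low values rest on the fewest fragments, and the effect of depth was not tested.

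Lists that came to stand apart are named by direction. For DP against nasal neutrophils, lysosome genes (3 settings), neurotrophic factors (1) and epithelial and olfactory markers (1) came to lie below. For nasal against blood neutrophils, chemoattractant receptors (3) and apoptosis regulators (1) came to lie above, and B and plasma cell markers, oxidative phosphorylation and ribosomal proteins (1 each) below. For DP against blood, eicosanoid synthesis (3), phagocytosis (2), macrophage markers, stromal markers and cytokines (1 each) came to lie above, and hypoxia and glycolysis (3), checkpoint molecules (2) and antioxidant genes (1) below.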

Other observations

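Lysosome genes did not stand apart between DP and nasal neutrophils (median 0.05, percentile 3.29), though they lay below the random range at percentiles of 2 with no filter, 2.21 at a mean of 5 FPKM or more and 1.26 without matching, but did between nasal and blood neutrophils (1.35, percentile 99.98). Lgmn, a lysosomal protease gene, stood at 165.9 FPKM in DP, 94.1 in nasal neutrophils and 6.09 in blood. In lipid handling, lower in DP than in nasal neutrophils (-0.69, percentile 0) and higher in nasal than in blood neutrophils (1.79, percentile 99.99), Dgat2, a triglyceride synthesis gene, stood at 22.3, 374.6 and 46 FPKM. Glycolysis and hypoxia genes were lower in DP than in nasal neutrophils (-0.56, percentile 0.01), with the lactate transporter gene Slc16a3 at 18.2 FPKM in DP and 515.4 in nasal neutrophils. Eicosanoid synthesis did not stand apart in any comparison (0.26 and percentile 18.1, 0.54 and 80.5, 1.4 and 91.5, for DP against nasal, nasal against blood and DP against blood), although it holds Ltc4s, and came to stand apart for DP against blood with pseudocounts of 0.1 (99.81) and 5 (97.92) and at a mean of 5 FPKM or more (98.76); Ptgs1 at 77.5, 7.75 and 5.32 FPKM and Cyp4f18 at 2406, 377.2 and 1094 were picked out after their values were seen.

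For DP against nasal neutrophils, the other lists lay as follows. Angiogenesis and matrix genes were at -0.91 (percentile 0), antioxidant and oxidase genes at -0.42 (0.84), class II presentation at -0.53 (0.58), phagocytosis at -0.33 (0.61, and 21 over genes at 1 FPKM or more in blood), apoptosis regulators at -0.1 (1.14, and 2.6 at a mean of 5 FPKM or more) and monocyte and dendritic markers at -0.88 (0.06). Macrophage markers were at -0.75 (0.08), B and plasma cell markers at -1.53 (0), stromal markers at -0.58 (0.69) and eosinophil markers at -1.5 (0.05). The unfolded protein response at 0.53 (31.2), cell cycle at 0.21 (15.6), housekeeping genes at 0.5 (42.1), T and NK cell markers at 0.43 (46.4), red cell and platelet markers at 0.69 (60) and epithelial and olfactory markers at 0.2 (11.7, and 2.24 without genes listed at 0 in 1 library and at 10 or more in both others) did not stand apart. Against blood, nasal neutrophils were higher in class II presentation (1.69, percentile 99.69), phagocytosis (2, percentile 100, 94.3 at a mean of 5 FPKM or more and 95.04 without genes at 0), primary granules (1.57, percentile 98.93, and 93 at that mean) and interferon response (0.91, percentile 99.73, and 95.6 without matching). The class II list shares members with the monocyte and dendritic cell markers (2.23, percentile 99.98), and the phagocytosis list with the macrophage markers (2.6, percentile 100). Both marker lists rose in the same comparison. Of the 9 phagocytosis genes at least 4-fold higher, 6 were listed at 0 in blood. Whether other leukocytes in the nasal library gave these values was not tested. Checkpoint molecules (1.04, percentile 97.98) had 10 members higher and 10 lower in nasal neutrophils and lay at percentile 52.5 at a mean of 5 FPKM or more 41.53 with no filter and 51.81 without genes at 0. The 5 eosinophil markers (1.9, percentile 97.86) lay at percentile 70.3 with no filter and are too few to rank without genes at 0. Mast cell and basophil genes Il3ra and Kit stood at 0.21 and 1.57 FPKM in DP, 3.64 and 5.21 in nasal neutrophils and 0.37 and 0.67 in blood.

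All tests in the next paragraphs were chosen after the results they bear on were seen. A bound on blood values was dropped from the test of shared reads because values listed at 0 met it. The tests of tissue RNA on oxidative phosphorylation and of dilution on granule genes were also revised after their outcomes were seen, the second of them 3 times. A bootstrap bound of 1.13 on the tissue list's median was replaced because it ignored the spread of the members. A granule percentile of 0 among 776 genes at 100 FPKM or more in blood was set aside over the concern that nasal tissue also expresses such genes, which was not tested. A count of markers past a fixed ratio was 7 with values as deposited, which went against dilution, and 4 once centred ratios were asked for as well, which left it open. The form kept counts markers relative to the granule genes, which no common scaling can move. Its outcome was known when it was chosen, so it weighs less than a test fixed in advance, and spread within either list can also raise its count.

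Olfactory and epithelial transcripts were in both nasal libraries although the gate asked for CD45 and Ly6G. RNA or cells of nasal tissue carried through the sort are a candidate source: 578 of 1118 olfactory receptor genes reached 0.1 FPKM in the nasal library with fewer of them, against 8 in blood, and the abundant tissue genes Obp1a (1073 and 1329 FPKM in DP and nasal neutrophils) and Omp (244 and 233.7) were present. Sharing of reads between related genes does not account for it, since 6 of 10 single-copy markers (Omp, Gng13, Cnga2, Cyp2g1, Epcam and Ncam1) were at 10 FPKM or more in both nasal libraries. Their blood values are not used, since 5 of the 6 are listed at 0 there. Transcription by the sorted cells themselves was not tested and stays open.

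Oxidative phosphorylation genes were higher in DP than in nasal neutrophils. A bias with transcript length as the whole cause is argued against by the list percentile of 100 after the length correction, with a median of 1.44 in place of 1.84. Nor was the length trend a matter of the nasal neutrophil library alone: short minus long transcripts differed by 0.8 for DP against nasal neutrophils and -0.34 for nasal against blood, but also by 0.54 for DP against blood. More nasal tissue RNA in DP may contribute and stays open: the tissue list had a median log2 ratio of 0.2 and an upper quartile of 1.34, below the 1.84 to be explained, but summed olfactory receptor genes stood at 1231 FPKM in DP and 392.5 in nasal neutrophils, a log2 ratio of 1.65. The day after LPS, the cell type and a batch cannot be told apart here.

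Granule protein genes were lower in DP than in nasal neutrophils, with a median of -2.05. Dilution of neutrophil RNA by tissue RNA would lower all neutrophil transcripts by 1 factor, which alone would not give the spread of ratios seen. Of 14 neutrophil markers outside that list, with a median of -1.14, 7 had log2 ratios more than 1 above the granule median. Among them were Csf3r (581.4 and 606.8 FPKM) and Il1r2 (2740 and 1996). The granule genes themselves ranged from -5.65 to 0.4, and Retnlg, outside that list, stood at 142.9 and 4692 FPKM. The count therefore does not set granule genes apart from other neutrophil transcripts, nor decide how much of their median dilution gives. Dilution was not tested for the inflammatory lists. Transcript length as the cause is argued against by a percentile of 0 after the length correction. With 1 library per group a real difference between the populations, the day after LPS and a chance difference between 2 samples may each account for the pattern and remain open, as does a part played by dilution.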
